A study of Oryza sativa Japonica Group with 18 samples.

How the data were processed

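Leaf RNA of 3 rice lines in 2 conditions was measured by RNA sequencing, with 3 libraries in each of 6 groups. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit from total RNA. The authors deposited 1 table of FPKM values (fragments scaled to gene length and to the total mapped) for 38610 genes in the 18 libraries. Bowtie 0.12.2 is named in the submitters' processing notes, while the genome build, the annotation, the counting tool and any filter are not given in the sources used here. Of the table's IDs, 35679 are locus IDs and 2931 are numbered new genes.

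FPKM values carry no read totals, so no counting interval is given. Relative depth was estimated from the most frequent ratio of low values to those of WT control replicate 1, with 17 to 47 values in support per library, which is few. Expression was analysed as log2(FPKM + 1), with no further normalization. Genes with an FPKM of at least 1 in at least 3 libraries were tested, 23175 in all, of which 1156 were new genes, and 15435 were left out.

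One model with 6 group means was fitted over the 18 libraries in limma 3.58.1 (R 4.3.3), with a variance trend and no covariates. It gave 9 comparisons, namely cold against control in each line, OX and RNAi against WT in each condition, and the differences of the OX and RNAi cold responses from that of WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Sets of genes were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, over 29 lists with at least 4 tested members, adjusted within each comparison. Genes called in OX and RNAi were set beside overlaps of independent lists and beside simulated groups without change that share a simulated WT group.

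The deposited table pairs IDs with no names. Gene names were written from background knowledge as 293 pairs of name and locus ID, and checked against the reference gene table of assembly ASM3414082v1, where 1 locus ID could be found directly. For 270 pairs the name belonged to a single reference gene on the same chromosome, and 269 of these also followed the order of the locus numbers. The lists kept 279 genes, 269 with a checked name. The tests, the rule for naming genes, the alternatives and part of the lists were chosen before the data were examined. The CBF/DREB1, cold-associated, jasmonate, circadian and secondary wall lists, the abscisic acid list except for 1 gene, and a few lists more belong to that part. The members of the remaining lists, mostly planned as searches of gene descriptions, were written after the table had been opened and before any comparison was run. In all, 19 of 29 planned lists could not be run as planned. The NAC, WRKY and MYB lists hold only members known by name, not whole families, and their results do not stand for the families. Members known by name may be known for stress responses, which was not checked, so a rise of such a list in the cold is weak support.

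Per comparison, the named genes were the 5 with the largest increase and the 5 with the largest decrease among called genes with a name, non-overlapping groups (not asked of the interactions) and a mean of at least 5 FPKM in the higher group, and up to 4 called members per list. Where no member was called, up to 2 with the smallest adjusted p could be named.

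The procedure was tested on simulated data with the means and spreads of the 23175 genes and 200 changed genes per comparison. For the cold response in WT it recovered 94% of genes changed by 2 on the log2 scale and 64% of those changed by 1, with 11 false calls. For the cold response of OX minus WT it recovered 74% and 31%, with 6 false calls. The highest share of false calls was 7.23%, with 12 false calls, for OX against WT before cold. Changed genes were drawn from those with a mean log2(FPKM + 1) above 2, and each gene varied independently. Recovery of low genes and the effect of a deviating library were therefore not tested. Alternatives were another pseudocount, filters, scalings, a test without the variance trend, library weights, a block for the replicate number, fits of the compared groups alone, a minimum fold change, other list tests, and leaving out each library.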

Results

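RNA was sequenced from leaves of rice seedlings at the 3-leaf stage, in wild type (WT), in plants overexpressing OsERF096 (OX), a gene of the ethylene response factor family, and in plants carrying an RNA interference construct against it (RNAi). Leaves were frozen either from normal growth (control) or after 12 h at 4 °C, which gave 6 groups of 3 libraries, 18 in all. The comparisons address how leaves of each line responded to cold, and how the transgenic lines differed from WT before and after it. The labels do not say whether the 3 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be technical. The deposited values were FPKM, with the absolute read depth unknown. Steps in the low values placed the libraries at 0.895 to 1.43 times the depth of the median library. Between 19597 and 20939 genes per library had an FPKM of at least 1. The row of OsERF096 itself was not analysed here, so the labels of the OX and RNAi libraries stand unchecked by their target.

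The first principal component held 54.8% of the variance and separated the cold from the control libraries. WT control replicate 2 stood apart on the second component (14.8%), at 88.4, and its mean correlation with the rest of its group was 0.92. Its 10 highest genes took 14.4% of the summed FPKM, against 8.66% and 8.69% in the other WT control libraries. In the OX and RNAi control libraries this share ranged from 8.66% to 13%, so it sets the library apart little. The secondary wall genes, which include the cellulose synthase gene CESA4, averaged 2.03 on the log2(FPKM + 1) scale in this library, against 5.67 and 5.99 in the rest of its group. Correlations between libraries of one group ranged from 0.915 to 0.988, and no pair of libraries held identical values.

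**Figure D1:**
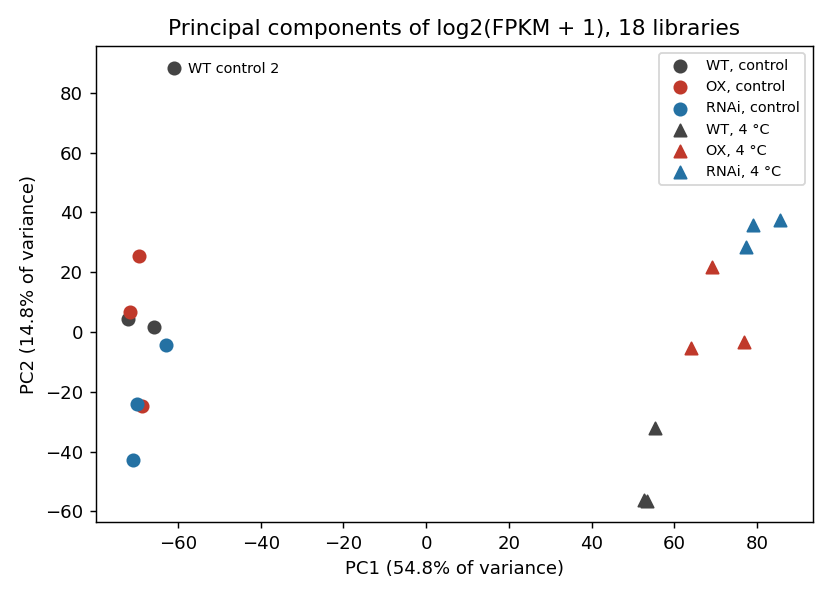
Principal components of log2(FPKM + 1) over the 18 libraries, with PC1 on the x axis and PC2 on the y axis, in arbitrary units. Each point is 1 library, circles are control and triangles 4 °C, and the point at 88.4 on PC2 is WT control replicate 2.

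In WT leaves, the CBF/DREB1 transcription factor genes of the cold response were higher after 12 h at 4 °C. DREB1A went from 0.718 ± 0.607 to 418 ± 14.2 FPKM (SD, n = 3), a log2 fold change of 7.98 ± 0.39 (SE), and DREB1B rose by 9.05 ± 0.65. ABA8OX1, which encodes an enzyme that breaks down abscisic acid, rose from 2.99 ± 2.92 to 1080 ± 152 FPKM. TIFY11A and TIFY11B, of the JAZ repressors of jasmonate signalling, rose by 7.04 ± 0.38 and 6.14 ± 0.40, and the transcription factor genes WRKY71 and MYB4 by 6.82 ± 0.64 and 6.46 ± 0.41. TPP1, which encodes a trehalose phosphate phosphatase, rose by 4.09 ± 0.24. The expansin gene EXPA2 fell by 3.43 ± 0.64, the protein phosphatase gene PP2C68 of abscisic acid signalling by 2.63 ± 0.41, and TIP4-1, an aquaporin of the vacuolar membrane, by 1.98 ± 0.18.

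All 7 CBF/DREB1 genes rose in WT, also when adjusted over the list alone (camera adjusted p = 1.45e-11, and adjusted p = 0.0409 with an estimated correlation). Of 16 jasmonate signalling genes 8 rose, 2 fell and 6 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.000423, but adjusted p = 0.476 with an estimated correlation). Of the 7 NAC genes listed by hand, not the whole family, 5 were higher and 1 lower. Among the higher were NAC6 at 3.58 ± 0.21 and NAC3 at 3.85 ± 0.42 (camera adjusted p = 0.00374, and adjusted p = 0.217 with an estimated correlation). Of 6 MYB genes 4 rose and 2 fell, with MYB2 at 3.81 ± 0.24 (camera adjusted p = 0.0181, and adjusted p = 0.194 with an estimated correlation; quantile normalization gave 0.0682). Of 11 aquaporin genes 9 fell and none rose, including PIP1-3 at -2.37 ± 0.61 (camera adjusted p = 0.0407, and adjusted p = 0.194 with an estimated correlation). The phenylpropanoid genes, 3 of 8 higher with ZB8 at 4.32 ± 0.50, passed camera with WT control replicate 2 (adjusted p = 0.0407) and not without it (0.472), and adjusted p = 0.542 with an estimated correlation.

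Across the genome, limma on log2(FPKM + 1) called 10595 of 23175 genes in WT, 3252 higher and 7343 lower, and 9548 without WT control replicate 2. In 55.4% of genes the groups of 3 did not overlap, where chance gives 10%. The time of day at freezing was not part of the comparison, so any share of it in these calls cannot be told apart from cold. Of the circadian clock genes, all given here, LHY was higher by 1.35 ± 0.38 and GI lower by -0.99 ± 0.13. PRR1 (-0.78 ± 0.28), PRR37 (-0.46 ± 0.14) and ELF3-1 (-0.41 ± 0.14) were also lower. Os01g0566100, without a checked name, was higher by 0.55 ± 0.17. PRR73, PRR95 and Os11g0157600 were not called. The median gene was lower by -0.22 on the log2 scale in cold WT leaves, -0.18 in cold OX leaves and -0.16 in cold RNAi leaves, so directions are relative to that shift. The share of called genes that were higher was 30.7% as deposited, 45.2% after quantile normalization and 48.1% after median-ratio scaling. Fold changes on the log2(FPKM + 1) scale understate those of low genes. How the deposited values split reads between close relatives such as DREB1A, DREB1B and DREB1H is not given in the sources used here.

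**Figure D2:**
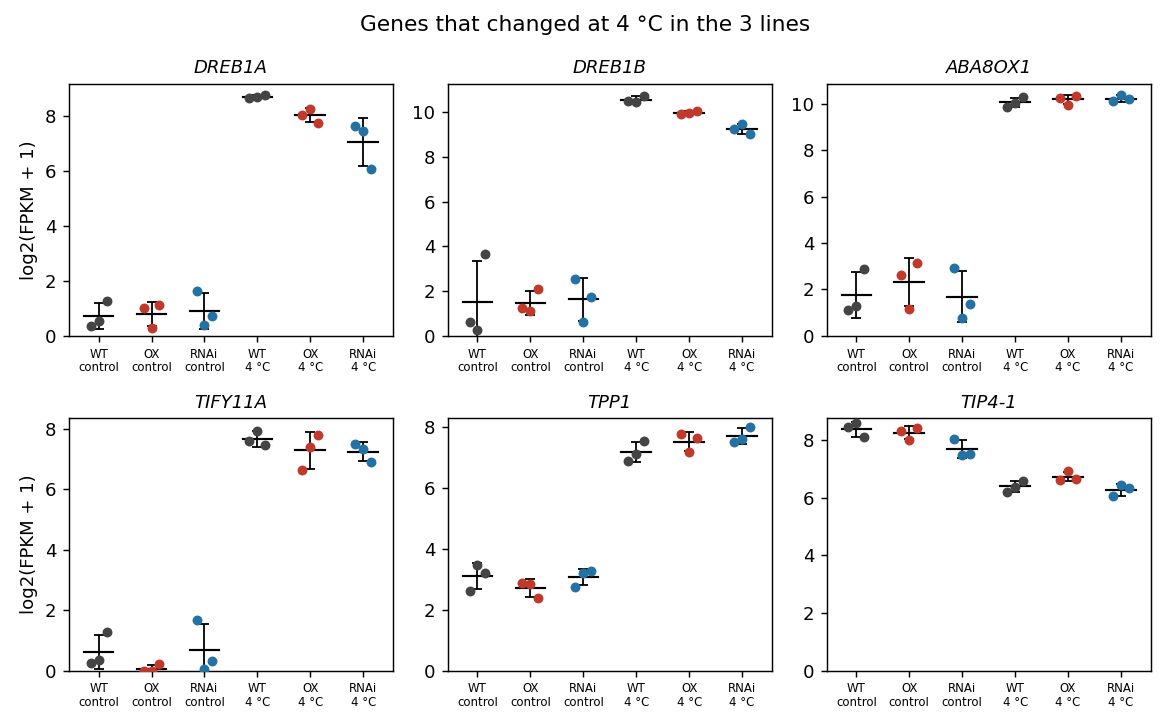
Expression of 6 genes in log2(FPKM + 1) on the y axis by group on the x axis. Points are libraries, and lines and bars are the mean and SD of 3 libraries. In WT, DREB1A went from 0.718 to 418 FPKM and TIP4-1 from 334 to 83.5 FPKM.

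The genes that led the cold response of WT leaves also rose in OX leaves. DREB1B rose by 8.49 ± 0.65, ABA8OX1 by 7.88 ± 0.54, TIFY11A by 7.22 ± 0.38 and WRKY71 by 7.01 ± 0.64. The dehydrin gene LIP9 rose by 3.09 ± 0.30, PP2C68 by 2.58 ± 0.41, the calcium-dependent protein kinase gene CPK13 by 3.94 ± 0.18 and ACS1, which encodes an enzyme of ethylene synthesis, by 4.76 ± 0.21. CAB1R, for a chlorophyll-binding protein of the photosynthetic antenna, fell by 2.28 ± 0.35, and PORA, for an enzyme of chlorophyll synthesis, by 2.13 ± 0.46.

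Among the lists in OX, all 7 CBF/DREB1 genes rose, also adjusted over the list alone (camera adjusted p = 1.28e-11, and adjusted p = 0.0356 with an estimated correlation). Of the 7 listed NAC genes 6 were higher, with NAC3 at 4.93 ± 0.42 and NAC5 at 2.92 ± 0.36 (camera adjusted p = 4.22e-07, and adjusted p = 0.0427 with an estimated correlation). Of 8 cold-associated genes 5 rose and 1 fell, or 6 and 1 adjusted over the list alone, with TPP1 at 4.81 ± 0.24 and the membrane protein gene LTI6B at 1.88 ± 0.26 (camera adjusted p = 0.00109, and adjusted p = 0.0356 with an estimated correlation). Jasmonate signalling had 10 of 16 higher and none lower, or 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.22e-07, and adjusted p = 0.183 with an estimated correlation). The abscisic acid pathway had 7 of 12 higher and none lower, the same adjusted over the list alone (camera adjusted p = 4.03e-05, and adjusted p = 0.122 with an estimated correlation). Of the 6 listed WRKY genes 5 were higher, with WRKY76 at 5.50 ± 0.47 (camera adjusted p = 0.000849, and adjusted p = 0.118 with an estimated correlation). In all, limma called 8343 genes in OX, 3150 higher and 5193 lower. The groups did not overlap in 44.7% of genes. The higher share was 37.8%, and 55.0% after median-ratio scaling.

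In cold RNAi leaves WRKY76 rose by 8.04 ± 0.47, to 402 ± 73.8 FPKM. ABA8OX1 rose by 8.53 ± 0.54, DREB1B by 7.60 ± 0.65, DREB1A by 6.15 ± 0.39 and the kinase gene MAPK5 by 5.24 ± 0.40. NCED3, which encodes an enzyme of abscisic acid synthesis, rose by 3.48 ± 0.36, PP2C68 by 4.13 ± 0.41 and LIP9 by 3.32 ± 0.30. PORA fell by 3.47 ± 0.46, its relative PORB by 1.94 ± 0.32, CHLI of the magnesium chelatase by 1.64 ± 0.21, and CAD2, of lignin synthesis, by 2.82 ± 0.64.

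All 7 CBF/DREB1 genes rose in RNAi too, also adjusted over the list alone (camera adjusted p = 7.25e-09, but adjusted p = 0.056 with an estimated correlation). Of 12 abscisic acid genes 9 rose and none fell, the same adjusted over the list alone (camera adjusted p = 1.34e-06, and adjusted p = 0.0713 with an estimated correlation). Jasmonate signalling had 9 of 16 higher and none lower, or 9 and 1 adjusted over the list alone (camera adjusted p = 1.42e-06, and adjusted p = 0.231 with an estimated correlation). The WRKY list had 5 of 6 higher (camera adjusted p = 3.31e-05, and adjusted p = 0.056 with an estimated correlation), and of 5 chlorophyll synthesis genes 4 fell (camera adjusted p = 0.0162, and adjusted p = 0.262 with an estimated correlation). For RNAi leaves limma called 10429 genes, 3920 higher and 6509 lower, with no overlap between the groups in 58.1% of genes. The higher share was 37.6%, and 53.4% after median-ratio scaling. The 4 secondary wall genes averaged 3.03, 4.23 and 2.97 on the log2(FPKM + 1) scale in the RNAi cold libraries, against 5.0, 5.43 and 5.15 in the RNAi controls. In WT they averaged 4.29, 4.81 and 4.07 in the cold, against 5.67, 2.03 and 5.99 in control replicates 1, 2 and 3. In OX they averaged 4.81, 5.69 and 5.37 in the cold, against 5.32, 5.45 and 5.71 in the controls.

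Over the 3 lines, 1710 genes rose in every line and 2555 fell in every line, while 974 changed in opposite directions in at least 1 pair of lines. WT and OX shared 1895 genes called higher, where independent lists of those sizes would share 442, and 3370 called lower, where they would share 1645. WT and RNAi shared 1798 higher, against 550, and 2968 lower, nearer to the 2062 of independent lists. OX and RNAi shared 2734 higher, against 533, and 3889 lower, against 1459.

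**Figure D3:**
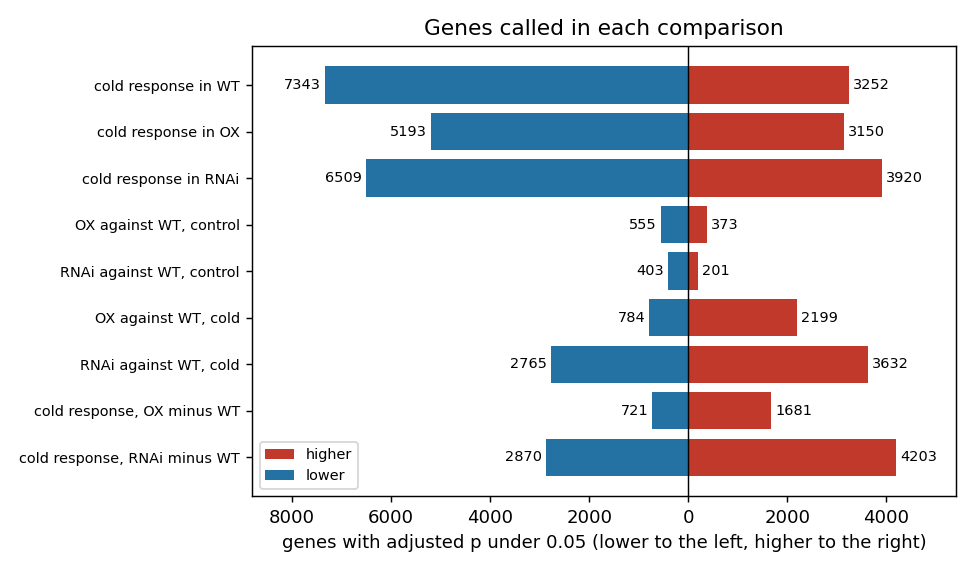
Number of genes with an adjusted p under 0.05 in each of the 9 comparisons, with lower genes to the left of 0 and higher genes to the right on the x axis. Cold called between 8343 and 10595 genes per line, and the lines differed from WT in 928 and 604 genes before cold.

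Before cold, OX leaves differed from WT in few named genes. TIFY11C was lower by -1.85 ± 0.45 and PP2C68 by -1.59 ± 0.41. The adjusted p of TIFY11C, 0.0308, passed 0.05 with all libraries and not when any 1 of the 6 was left out (up to 0.0891). For PP2C68 the call (adjusted p = 0.0426) ended without WT control replicate 1, 2 or 3 or OX control replicate 2 or 3, with an adjusted p up to 0.138 over all alternatives. The largest called changes included genes with no name in the sources used here, where Os04g0116800 was higher by 6.11 ± 0.45 and Os11g0696600 lower by -6.30 ± 0.13. No list passed camera, where auxin response came closest (adjusted p = 0.0629, no member called of 22). limma called 928 genes, 373 higher and 555 lower, and 19.2% of genes did not overlap. The count was 550 without WT control replicate 1, 575 without WT control replicate 3 and 398 without OX control replicate 3, and 190 when only these 6 libraries were fitted.

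RNAi leaves before cold were lower than WT in phosphatase genes of abscisic acid signalling. PP2C68 was at 1.47 ± 1.07 FPKM against 13.3 ± 2.66 in WT, a log2 fold change of -2.61 ± 0.41, and PP2C50 was lower by -1.14 ± 0.18 and PP2C30 by -1.62 ± 0.36. P5CS2, which encodes an enzyme of proline synthesis, was lower by -1.80 ± 0.31, NAC5 by -1.61 ± 0.36, and the small heat shock protein gene HSP24.1 was higher by 1.23 ± 0.20. Of 12 abscisic acid genes 4 were lower and none higher, or 7 lower adjusted over the list alone (camera adjusted p = 0.000527, but adjusted p = 0.688 with an estimated correlation).

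Over all genes limma called 604 in RNAi control leaves, 201 higher and 403 lower, with no overlap in 27.7% of genes. The higher share was 33.3%, and 50.7% after quantile normalization or 44.4% after median-ratio scaling. The count depended on single libraries and was 201 without WT control replicate 2, 1001 without RNAi control replicate 1, 118 without RNAi control replicate 2 and 160 without RNAi control replicate 3. When only these 6 libraries were fitted it was 50, and PP2C68 (adjusted p = 0.0727), PP2C50 (0.0867), P5CS2 (0.159) and HSP24.1 (0.132) were no longer called. PP2C30 and NAC5 also lost their calls without WT control replicate 2 or RNAi control replicate 2 or 3, and PP2C30 without WT control replicate 3 (adjusted p up to 0.16 and 0.21).

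In the cold, OX leaves held more transcript than WT of several stress genes. PP2C68 was at 28.4 ± 9.87 FPKM in OX and 1.30 ± 0.275 in WT, a log2 fold change of 3.62 ± 0.41. NAC5 was higher by 2.93 ± 0.36, LIP9 by 2.06 ± 0.30, RR9, a cytokinin response regulator gene, by 2.07 ± 0.44, ACS1 by 1.79 ± 0.21 and CPK13 by 1.51 ± 0.18. LTI6B was higher by 1.27 ± 0.26 and the ethylene receptor gene ERS1 by 0.73 ± 0.13. None of the 7 CBF/DREB1 genes was called. Of 5 chlorophyll synthesis genes 2 were lower and none higher (camera adjusted p = 0.0228, but adjusted p = 0.413 with an estimated correlation).

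For OX against WT in the cold, limma called 2983 genes, 2199 higher and 784 lower, and 38.0% did not overlap. The higher share was 73.7%, and 54.2% after quantile normalization. The count was 1321 without WT cold replicate 1, 1594 without WT cold replicate 2, 1969 without OX cold replicate 2 and 1786 without OX cold replicate 3.

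RNAi leaves in the cold also held more PP2C68 and NAC5 transcript than WT, by 4.15 ± 0.41 and 3.21 ± 0.36. WRKY76 was higher by 3.73 ± 0.47, NCED3 by 2.35 ± 0.36, CPK13 by 1.98 ± 0.18 and P5CS2 by 1.44 ± 0.31. PORA was lower by -2.95 ± 0.46 and PORB by -1.23 ± 0.32. DREB1A stood at 147 ± 71 FPKM against 418 ± 14.2 in WT (log2 fold change -1.65 ± 0.39), and DREB1H was lower by -1.83 ± 0.33. With a pseudocount of 0.1 these 2 genes missed the threshold (adjusted p = 0.0641 and 0.0661). Of 7 CBF/DREB1 genes 2 were lower, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.077).

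Of 5 chlorophyll synthesis genes 4 were lower in RNAi than in WT (camera adjusted p = 0.0139, but adjusted p = 0.416 with an estimated correlation). Of 6 WRKY genes 5 were higher, with WRKY62 at 2.15 ± 0.42 and WRKY51 at 1.47 ± 0.32 (camera adjusted p = 0.0139, and adjusted p = 0.416 with an estimated correlation). limma called 6397 genes in this comparison, 3632 higher and 2765 lower, and 48.2% did not overlap. The count was 4068 without WT cold replicate 1 and 4174 without WT cold replicate 2.

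Among genes with a checked name, PP2C68 had the largest difference between cold responses, tested as an interaction, in both transgenic lines. Its transcript fell in cold WT leaves and rose in both others, so that the response was higher by 5.21 ± 0.58 in OX and by 6.76 ± 0.58 in RNAi than in WT. NAC5 responded more by 3.86 ± 0.51 in OX and 4.82 ± 0.51 in RNAi, and LIP9 by 2.31 ± 0.43 and 2.54 ± 0.43. P5CS2 responded more by 2.03 ± 0.44 in OX and 3.25 ± 0.44 in RNAi, and CPK13 by 2.05 ± 0.26 and 2.33 ± 0.26. In RNAi, WRKY76 responded more by 4.18 ± 0.66 and NCED3 by 3.25 ± 0.51, and PORA less by -3.65 ± 0.66.

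Of 12 abscisic acid genes 4 responded more in OX than in WT, or 5 adjusted over the list alone (camera adjusted p = 0.0163, but adjusted p = 0.507 with an estimated correlation). In RNAi 6 did, or 7 adjusted over the list alone (camera adjusted p = 0.00398, but adjusted p = 0.368 with an estimated correlation). limma called 2402 genes for OX, 1681 more positive and 721 more negative than in WT, and 7073 for RNAi, 4203 and 2870. The more positive share for OX was 70%, and 54.2% after quantile normalization, and for RNAi 59.4%, and 50% after it. Left-out libraries took the OX count to 1078 (WT cold replicate 1), 1255 (WT cold replicate 2) and 1385 (OX cold replicate 2), and the fit of these groups alone to 1563.

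**Figure D4:**
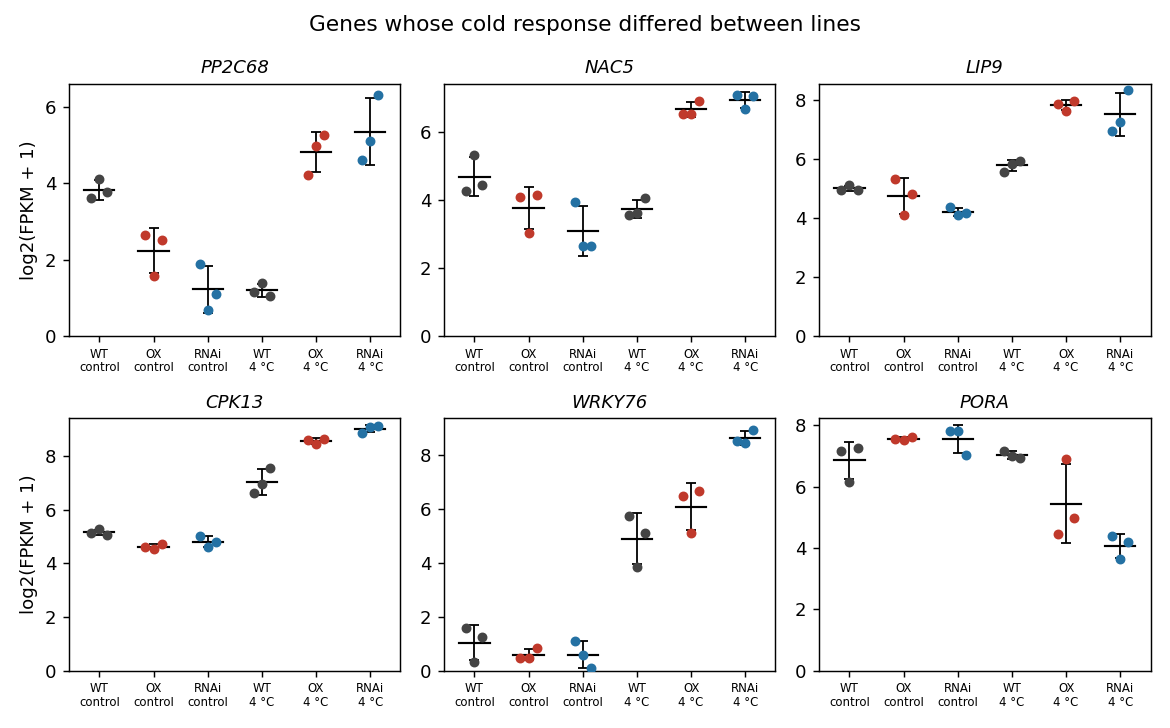
Expression of 6 genes in log2(FPKM + 1) on the y axis by group on the x axis, with points for libraries and lines and bars for the mean and SD of 3. PP2C68 was at 13.3 FPKM in WT control and 1.30 in WT cold leaves, and at 45.3 FPKM in RNAi cold leaves.

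Overexpression and knockdown of one gene pose the question of opposite changes. In the cold, 41 genes moved in opposite directions from WT in OX and RNAi, and 2106 moved the same way, 1590 of them higher and 516 lower, where independent lists would share 344.6 and 93.5. The 41 were fewer than the 262.4 (higher in OX) and 122.9 (lower in OX) that independent lists would hold in opposite directions, but the lists share their WT libraries, and unchanged groups simulated with a shared WT group gave at most 0 opposite and 1 same-way gene in 5 fits. Part of the 41 lay in the runs of OX genes along the chromosomes described further below. Of the 68 genes in those runs, 15 were called the opposite way in RNAi in control or cold leaves. For these, OsERF096 cannot be told apart from a segment or tissue culture change peculiar to the OX line. PP2C68, NAC5 and LIP9 were among the genes higher in both lines. Across genes, which are not independent replicates, the 2 sets of fold changes had a covariance of 0.247 and r = 0.686. Unchanged groups simulated with a shared WT group gave 0.0244 and 0.458, and part of the excess may come from the shared controls. The count of 2106 became 914 without WT cold replicate 1, 1105 without WT cold replicate 2 and 1365 without OX cold replicate 3, and the count of 41 became 23 without WT cold replicate 1 and 22 without WT cold replicate 2.

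Before cold, 4 genes moved in opposite directions, where independent lists would hold 6.5 and 4.8, and 202 the same way. The 5 simulated fits gave at most 0 and 36. The covariance was 0.125 against 0.0725 simulated, and r = 0.56 against 0.641. The simulation, like that for the cold, drew each gene independently, so it holds no deviation of a whole library. Regrouping the real libraries gave as many as 202 same-way genes in 6 of 100 splits (highest other 1271), so chance cannot be excluded for them. The count of 202 was 92 without WT control replicate 2, 107 without OX control replicate 3, 64 without RNAi control replicate 2 and 83 without RNAi control replicate 3. The 4 became 1 without WT control replicate 2 or RNAi control replicate 3, and 2 without RNAi control replicate 1 or 2. A single gene, named here after its values were seen, was opposite with the same signs in both conditions: Os03g0426350 was at 1.27 and 1.03 in OX, and at -4.26 and -4.20 in RNAi.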

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

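The counts, genes and lists of the interactions below were selected because the cold response of a transgenic line differed from that of WT by a test of the difference itself. The tests of what lies behind the far-apart genes, the runs of genes and the genes moving the same way, and the list tests without single libraries, were chosen after results had been seen.

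For OX the cold response differed from WT in 2402 genes, and 2 of 100 splits of the libraries, the real one included, gave as many (highest other 2456). The highest other split also divided the cold libraries by line and mixed the control libraries, and 41 of the 99 others called any gene. The splits address any difference between the lines, in either condition, and cannot decide whether the cold response itself differs. PP2C68 differed by 5.21, NAC5 by 3.86, LIP9 by 2.31, CPK13 by 2.05, P5CS2 by 2.03, ACS1 by 1.77, PP2C50 by 1.15 and ERS1 by 0.97 on the log2 scale. The abscisic acid list passed camera (adjusted p = 0.0163, but adjusted p = 0.507 with an estimated correlation). The ethylene list (adjusted p = 0.0454, and adjusted p = 0.305 with an estimated correlation) included EIN2, whose libraries lay far apart within groups. It lost its call without WT control replicate 2 or 3, OX control replicate 1 or OX cold replicate 3 (adjusted p up to 0.0822). As many as 2 lists were called in 64 of 100 splits (highest other 9), so chance cannot be excluded for the lists.

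For RNAi the response differed in 7073 genes, and 1 of 100 splits gave as many, the real one (highest other 4797). That highest other split also divided the cold libraries by line, and only 17 of the 99 others called any gene. For the reason given for OX, the splits cannot decide whether the cold response itself differs. PP2C68 differed by 6.76, NAC5 by 4.82, WRKY76 by 4.18, PP2C30 by 3.53, RAB21 by 3.31, NCED3 and P5CS2 by 3.25, RR9 by 3.23, CKX4 by 3.14, LIP9 by 2.54 and CPK13 by 2.33. PORA differed by -3.65, SODCP by -2.06, DREB1A by -1.83 and DREB1H by -1.70, and the DREB1 genes were not called with a pseudocount of 0.1 (adjusted p = 0.103 and 0.176). The abscisic acid list (adjusted p = 0.00398), the chlorophyll synthesis list and the WRKY list (adjusted p = 0.0194 each) passed camera and none did with an estimated correlation (adjusted p = 0.368 each). As many as 3 lists were called in 59 of 100 splits (highest other 9), so chance cannot be excluded for the lists.

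In 248 of 11903 genes with a group mean of at least 10 FPKM, libraries of one group lay at least 8-fold apart on the FPKM + 1 scale, with 313 outlying values. WT control replicate 2 held 51.8% of these values, in line with 1 deviating library as the source of that part. A mislabelled OX library is argued against, since 37 of 37 genes (100%) under 0.5 FPKM in all 6 OX libraries and at 2 FPKM or more in the 5 other WT libraries reached 0.5 FPKM in it, while the 13.2% of 38 genes differing in the cold that lay nearer the OX control mean decide nothing alone. Less secondary wall tissue in this library stays open as a hypothesis: the 100 genes that follow the secondary wall genes over the other 17 libraries were lower by a median of -1.68, with quartiles of -2.58 and -0.55 that are too wide to decide.

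Genes that differed from WT in OX in both conditions lay in runs when ordered by locus number: 65 neighbouring pairs stood against at most 14 in 10000 random placements (permutation p = 1e-04, the smallest they can give), which argues against chance placement, and 50 of the 192 with a locus number lay on chromosome 11. Variant alleles whose reads fail to align stay open: of the 68 genes in runs 29.4% were higher in OX, but 10 of these 20 were under 0.5 FPKM in all WT libraries, as alleles of WT that fail to align would be, and 34 of the 48 lower ones were under 0.5 FPKM in all 6 OX libraries, as lost or silent genes would be too. A change common to both transgenic lines is argued against for most of these 68 genes, of which 7.35% were called the same way in RNAi control leaves (exact 95% interval 2.43 to 16.3; median ratio of the RNAi to the OX log2 fold change 0.02). It stays open for the RNAi line, whose genes also lay in runs (13 neighbouring pairs against at most 6), as 50% of the 12 genes in them were called the same way in OX control leaves (interval 21.1 to 78.9). The overexpressed factor acting on neighbouring genes, the biological explanation, cannot be told apart from a segment or a tissue culture change peculiar to this line, since 22.1% were called the opposite way in RNAi in control or cold leaves and overexpression need not mirror knockdown.

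In the cold, 2106 genes moved the same way in OX and RNAi and 41 in opposite directions. Scaling as the cause is argued against, since under both scalings those moving the same way were at least 44.8 times as many. WT cold leaves taken at another time of day were looked at through the clock genes. Over both lines, the 9 tested circadian clock genes lay at percentile 18 of 10000 random lists matched on expression. The percentile cannot decide, since another time of day could move the genes of the random lists too. In OX the clock genes had a median absolute log2 fold change of 0.06 (percentile 0.13) with none called. This little difference argues against another time of day between the WT and OX cold leaves. In RNAi the median was 0.36 (percentile 42.7) with 2 called, so between the WT and RNAi cold leaves another time of day stays open. A deviation common to the WT cold libraries cannot be told apart from a change common to both transgenic lines: the covariance exceeded the simulated one by 0.222, and the simulation holds no such deviation. A response common to both lines stays among the open explanations, as untested.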

How the results depend on the processing

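Of the tests here, the fit without genes whose libraries lie far apart and the list tests without single libraries were added after the data were seen. No named gene or list that was called changed direction under an alternative, but the majority of calls did: higher genes outnumbered lower ones under median-ratio scaling for cold in OX (4139 and 3387) and RNAi (5287 and 4610), under a minimum log2 fold change of 1 for cold in OX (1853 and 1597), and for RNAi against WT before cold under quantile normalization (317 and 308) and in a fit of the compared groups alone (27 and 23). A minimum log2 fold change of 1 took the cold counts to 4493 (WT), 3450 (OX) and 4532 (RNAi), OX and RNAi against WT to 425 and 259 before and to 1136 and 2203 in the cold, and the interactions to 1366 (OX) and 4365 (RNAi), by its construction. It left 1 opposite and 79 same-way genes before cold, and 14 and 688 in the cold. Library weights gave 1538 and 6172 genes against WT before cold, 6714 and 10082 in the cold, 3628 and 10806 for the interactions, 26 opposite and 778 same-way genes before cold, and 109 and 4509 in the cold, and the cause was not tested. Fitting only the compared groups, with fewer libraries to estimate the spread, gave 190 and 50 genes before cold, 1563 for the OX interaction, and 1 opposite and 12 same-way genes before cold. An FPKM filter at 5, which tests fewer genes, gave 569 for OX before cold and 125 same-way genes. Opposite genes before cold were 7 under quantile normalization and 2 with a pseudocount of 0.1. Without single libraries, counts ranged from 8614 to 9919, 6775 to 8368 and 8732 to 9385 for cold in WT, OX and RNAi, from 398 to 1030 and 118 to 1001 for OX and RNAi against WT before cold, from 1321 to 2785 and 4068 to 5666 in the cold, and from 1078 to 2428 and 5113 to 7072 for the interactions. Opposite and same-way genes ranged from 1 to 4 and 64 to 242 before cold, and from 22 to 36 and 914 to 1999 in the cold. A library left out leaves 2 in its group, assumed to vary like the others. Without genes whose libraries lie far apart, the counts stayed within 1.5 times. Of 47 list calls over the comparisons, 4 held with an estimated correlation, while fry, which asks another question, gave 97, and single left-out libraries gave 41 to 56. Over all alternatives, the named genes followed kept their calls in 2002 cases and lost them in 35, and list results kept theirs in 487 and lost them in 81. Replicate numbers did not pair the libraries: of 45 same-number pairs 14 correlated above 0.1 (range -0.60 to 0.41), and 7 of 18 libraries correlated best with their own number. A replicate block took RNAi against WT before cold from 604 to 373 genes and opposite genes to 2. It ended the calls of PP2C68 in OX (adjusted p = 0.0526) and PP2C30 in RNAi (adjusted p = 0.0554) before cold, kept the 47 list calls and gave 49. Among the named genes followed and the called lists the block changed no other call, while the other counts stayed within 1.5 times. For 3 against 3 libraries only 10 splits exist, which cannot give a share under 0.05. Each other split also put libraries of both real groups on the same side. Where the real groups differ, this widens the spread, so low counts in the other splits were built in and decide nothing. The real count and the highest of the other splits were 10595 and 6 for cold in WT, 8343 and 1 in OX, 10429 and 0 in RNAi, 604 and 1 for RNAi before cold, 2983 and 1 for OX in the cold, and 6397 and 0 for RNAi in the cold. For OX before cold they were 928 and 1296, the latter with WT control replicate 2 grouped with OX control replicates 1 and 3, which points to a structure of the samples. Lists called and the highest other were 8 and 8, 11 and 10, and 10 and 10 for cold, 0 and 11 and 1 and 10 before cold, and 5 and 4 and 7 and 4 in the cold. For same-way genes before cold 6 of 100 splits gave as many as 202 (highest other 1271), so chance cannot be excluded. For same-way genes in the cold (2106, highest other 533) and for opposite genes before cold (4, highest other 0) and in the cold (41, highest other 0), 1 of 100, the real one, gave as many, which decides little, since only 17 of the 99 others before cold and 5 in the cold called any gene in both lines. Read depth was unknown, which limits what can be said of low genes.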

Other observations

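Of the tests here, that of neighbouring genes was planned before its result was seen, but its bound was made stricter afterwards, and the genes and lists were picked after results were seen. Some expansin genes, of cell wall loosening, and some cytokinin genes were higher in cold RNAi leaves than in cold WT leaves. Of 7 expansin genes 5 were higher and none lower, with EXPB4 at 3.19 ± 0.67 and EXPB3 at 2.66 ± 0.46 on the log2 scale (SE, n = 3, limma; camera adjusted p = 0.0247, but adjusted p = 0.54 with an estimated correlation). In cold WT leaves EXPB4 had fallen by 2.59 ± 0.67. Of 8 cytokinin genes 4 were higher, with the response regulator gene RR6 at 2.55 ± 0.54 and the cytokinin oxidase gene CKX4 at 1.67 ± 0.33 (camera adjusted p = 0.0396, but adjusted p = 0.541 with an estimated correlation). Of 10 antioxidant genes 1 was higher and 5 lower, with the superoxide dismutase genes SODCP at -1.49 ± 0.31 and SODCC2 at -0.88 ± 0.14 and the ascorbate peroxidase gene APX1 at 0.76 ± 0.19 (camera adjusted p = 0.0326, but adjusted p = 0.54 with an estimated correlation). Without RNAi cold replicate 3 these lists were not called (adjusted p = 0.0529 for expansins and antioxidants), and the cytokinin list was not called without WT cold replicate 1 either (adjusted p up to 0.0678).

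Other genes of hormone and heat responses also changed in cold WT leaves. The auxin response gene IAA23 rose by 3.66 ± 0.32 and the heat shock factor gene HSFA3 by 3.95 ± 0.23 (SE, n = 3, limma). RR4, a cytokinin response regulator gene, fell by 2.0 ± 0.28. Of jasmonate synthesis, AOC fell by 1.16 ± 0.20, while AOS2 and AOS1 rose by 1.84 ± 0.63 and 1.67 ± 0.52 and OPR7 was not called.

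EIN2, of ethylene signalling, and RBCS, for the small subunit of Rubisco, jumped between libraries of one group. EIN2 was at 8.93, 0.56 and 0.38 FPKM in WT cold replicates 1, 2 and 3, and RBCS at 15466.39, 1626.88 and 11056.45 FPKM in OX cold replicates 1, 2 and 3. The hypothesis that reads moved between neighbouring genes was tested over 239 genes with a locus number. These were among the 248 genes at least 8-fold apart within a group of mean 10 FPKM or more. RBCS was among the 248, and EIN2 was not, as its far-apart groups did not reach that mean. In 30.1% at least 1 of the 4 nearest tested genes with a locus number deviated the opposite way (correlation below -0.5), against 33.5% to 48.5% with random genes. This argues against reads moved between such neighbours as the source for most of the 239 genes. New gene rows and rows further away were not looked at, so for RBCS singly the hypothesis stays open. It also stays open for EIN2, which was outside the test.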
